A study of Homo sapiens with 3 samples.

How the data were processed

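RNA of FaDu cells was profiled on 3 Affymetrix PrimeView arrays, 2 from untreated cells, incubated with distilled water, and 1 from cells kept for 48 h with NSC-631570 at 10 µg/ml. Per the labels, RNA was isolated with the RNeasy kit and 100 ng were amplified and labelled with biotin by the IVT Express kit. The deposited values are log2 signals, 1 per probe set and array, and were made by the authors with Affymetrix Expression Console, per the labels. The algorithm, its settings and the version are not given in the sources used here. That the scale is log2 was read from the deposited values, which run from 2.92 to 14.95 in untreated 1 and over nearly the same range in the other arrays. The medians of the 3 arrays lay within 0.07 of each other, but their distributions were not identical. How the arrays were normalized is not given in the sources used here. The values were used as deposited. Single-probe intensities and background estimates were not used here, so detection could not be called per probe set, and the number of arrays limits the precision.

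Probe sets were named through the platform's annotation table. Of 49395 probe sets, 102 are array controls, 44994 named 1 gene, 1832 named several and 2473 named none here. Gene symbols of the fixed lists were brought up to date with the RefSeq gene table. Probe sets naming several genes were not used for any gene. Each of 18132 genes was represented by the probe set with the highest mean over the 3 arrays. Genes whose mean lay below the 40th percentile of all probe sets (5.85) were left out, which left 11933. Values of other probe sets past the same filter are given beside some of the named genes, chosen after the values were seen. No genome coordinates are given, since the sources used here name no genome build.

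Treated and untreated arrays were compared with limma (version 3.58.1, R version 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The residual variance has 1 degree of freedom, from the untreated arrays, and was moderated across genes with 6.93 prior degrees of freedom around a prior SD of 0.19. The treated array is assumed to vary like the untreated ones. A second rule without a test counted genes at least 2-fold above or below both untreated arrays, and repeated the count with each untreated array in the place of the treated one. The untreated arrays were compared with each other before they were averaged: 158 tested genes differed at least 2-fold between them. The labels do not say whether they came from separate cultures.

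Gene lists had been fixed before the data were examined, 36 in number with 737 symbols, of which 672 were named here and 602 tested. Lists with at least 5 tested members, 35 of them, were compared with the other genes by camera with a preset correlation of 0.01, adjusted over the lists. This preset treats the members of a list as almost independent, so its p-values measure spread between genes, not between arrays. Camera was also run with a correlation estimated from the data. That version rests on the 1 residual degree of freedom and could hardly call any list, so its adjusted p-values say little either way. Each list median was also placed among the medians of 10000 random lists of the same size, matched on mean expression. This draws genes, not arrays, so its p-values measure no spread between arrays and ignore correlation between members. Members were tested over all genes and again adjusted over the list alone. The fibroblast markers had 3 tested members and were not tested as a list.

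The genes named in the text followed a rule fixed before the data were examined: the 12 higher and 12 lower genes with the largest difference from the nearer untreated array among those past the threshold, filled up by the same ranking where fewer pass, and up to 4 members of each described list with the largest log2 difference. Genes with only cross-hybridising probe sets were left out of the ranking. Genes named outside this rule are marked as such.

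The fit and the list test were tested on simulated arrays of 11933 genes with the measured means and a spread drawn from the fitted prior variance. Of genes changed 2-fold, 18 of 50 were recovered, and all 50 of those changed 4-, 8- and 16-fold, beside 21 unchanged genes called. Among 20 simulated sets without any change, 7 had at least 1 call. A shifted list was called and no other list was. Genes were simulated as independent of each other and without a shift of all genes. False list calls from correlated members or from such a shift could therefore not appear. The alternatives tried were other normalisations and centrings, other filters, the mean of a gene's probe sets, probe sets one by one, other prior variances, a test against a bound of 0.5, a 1.5-fold rule, an estimated correlation and leaving out each untreated array. A second pseudocount had been planned for linear values only and was not needed.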

Results

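The study asked how an extract of greater celandine (Chelidonium majus), registered as NSC-631570, changes gene expression in FaDu cells, an established line from a squamous carcinoma of the hypopharynx. One culture had been grown for 48 h with 10 µg/ml of the extract, described by the submitters as its half-maximal effective dose, and control cells had been grown without it. Total RNA was hybridised to human PrimeView arrays, which hold several probe sets for most genes, and gave 2 untreated arrays and 1 treated array. Signals are log2 values per probe set. The array medians were 6.62 and 6.57 for the untreated arrays and 6.55 for the treated array. Of 49395 probe sets, 44994 named 1 gene. They covered 18132 genes, of which 11933 had signal above the filter and were tested. The treated condition has no replicate, so its own spread is unknown and the tests assume that it varied like the untreated arrays. Nothing in the labels says that the untreated arrays came from separately grown cultures, so p-values may measure technical spread alone.

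Of the 8 genes past the limma threshold, 3 enzymes of xenobiotic metabolism, ISG20 and SPOCK1 were higher in the treated array, and CBX5, the matricellular growth factor gene CCN2 and SNORD17 were lower. CYP1A1, a cytochrome P450 that is the classical target of the aryl hydrocarbon receptor (AhR), was 23.8-fold higher (log2 difference 4.57 ± 0.22, SE from limma, 2 untreated arrays against 1 treated array). Its signal was 5.99 and 6.10 in the untreated arrays, near the filter of 5.85 and below the array medians, and 10.62 in the treated one. CYP1B1, a related P450 enzyme with untreated signals of 6.55 and 6.47, was 5.33-fold higher (2.42 ± 0.22). No detection call was made for any gene, so the folds of CYP1A1 and CYP1B1, and of other genes this near the filter, are ratios of signals whose untreated level was not shown to be above background. ALDH3A1, an aldehyde dehydrogenase of the same response, was 3.93-fold higher (1.98 ± 0.22). ISG20, an interferon-induced exoribonuclease, was 5.30-fold higher (2.41 ± 0.21), and SPOCK1, a secreted matrix proteoglycan, was 3.84-fold higher (1.94 ± 0.21). CCN2, also known as connective tissue growth factor, was 5.71-fold lower (−2.51 ± 0.21), with 9.95 and 9.90 in the untreated arrays and 7.41 in the treated one. SNORD17, a small nucleolar RNA, was 3.94-fold lower (−1.98 ± 0.22). CBX5, which encodes a heterochromatin protein, was 5.99-fold lower (−2.58 ± 0.28) on its brightest probe set, but the median of its 6 other probe sets was 0.23 higher on the log2 scale, and the mean of all its probe sets differed by −0.34 (adjusted p = 0.473). The other probe sets of CYP1A1 (2.49, 1 probe set), CYP1B1 (median 2.17, 3 probe sets) and CCN2 (median −2.50, 2 probe sets) differed the same way as the ones tested. ISG20, ALDH3A1, SPOCK1 and SNORD17 had no other probe set to compare.

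These 8 genes, 5 higher and 3 lower, are those past the threshold of limma with Benjamini-Hochberg adjustment. In simulations without any change 7 of 20 sets had a call, so adjusted p-values here may be too small. The adjusted p was 0.00036 for CYP1A1, 0.0115 for ISG20, CYP1B1 and CCN2, and 0.0283 for ALDH3A1, SPOCK1, SNORD17 and CBX5. At an unadjusted p under 0.05 limma counted 1724 genes, 1456 higher and 268 lower. With genes taken by their brightest probe set, the median tested gene was 0.12 above the untreated mean, although the treated array had the lowest median over all probe sets. Of 11933 tested genes, 7875 lay above the untreated mean and 4058 below it, so counts of list members are to be read against that share. The count of genes past the threshold depended on the scaling: it was 4 (3 higher, 1 lower) after quantile normalisation, 136 (111 higher, 25 lower) with arrays brought to a common median over all probe sets, and 50 (21 higher, 29 lower) with a common median over the tested genes. ALDH3A1, SPOCK1, SNORD17 and CBX5 missed the threshold after quantile normalisation, without a filter, with the mean of a gene's probe sets and against a bound of 0.5, and CYP1B1 missed it with the mean of its probe sets (adjusted p = 0.0786).

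The next genes by distance from the nearer untreated array did not pass the threshold (adjusted p between 0.0632 and 0.089). Above both untreated arrays were CTHRC1, a secreted collagen-repeat protein (log2 difference 1.79, 3.46-fold), S100P, a calcium-binding protein (1.75), DHX58, an interferon-induced RNA helicase (1.64), GALNT12, which starts mucin-type glycans (1.63), PRR15 (1.61) and GAA, the lysosomal alpha-glucosidase (1.52). VAT1 stood 1.63 above on its brightest probe set, and its other probe set was 0.41 below (−0.41). Below both were BPNT1 (−1.89), the HSP70-HSP90 cochaperone STIP1 (−1.72), the RAS GTPase-activating protein gene RASAL2 (−1.69), the NF-kB subunit REL (−1.68), the protease CAPN1 (−1.57), the zinc transporter SLC39A7 (−1.49), the 14-3-3 protein gene YWHAE (−1.39), the transcription factor USF1 (−1.38) and the pyruvate kinase PKM (−1.25, 2.38-fold). Other probe sets of STIP1 (−2.24) and REL (−1.93) were lower too. In the treated array, which gave the higher and the lower values alike, the 5′ control probe set of ACTB was 2.59-fold lower. For RASAL2 the median of the other probe sets was −0.23 and for CAPN1 it was −0.32. Taken as the mean of all probe sets of the gene, the difference was 1.08 for CTHRC1, 0.88 for DHX58, 0.74 for GAA, 0.61 for VAT1, −1.04 for BPNT1, −0.94 for CAPN1 and −0.44 for RASAL2.

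**Figure D1:**
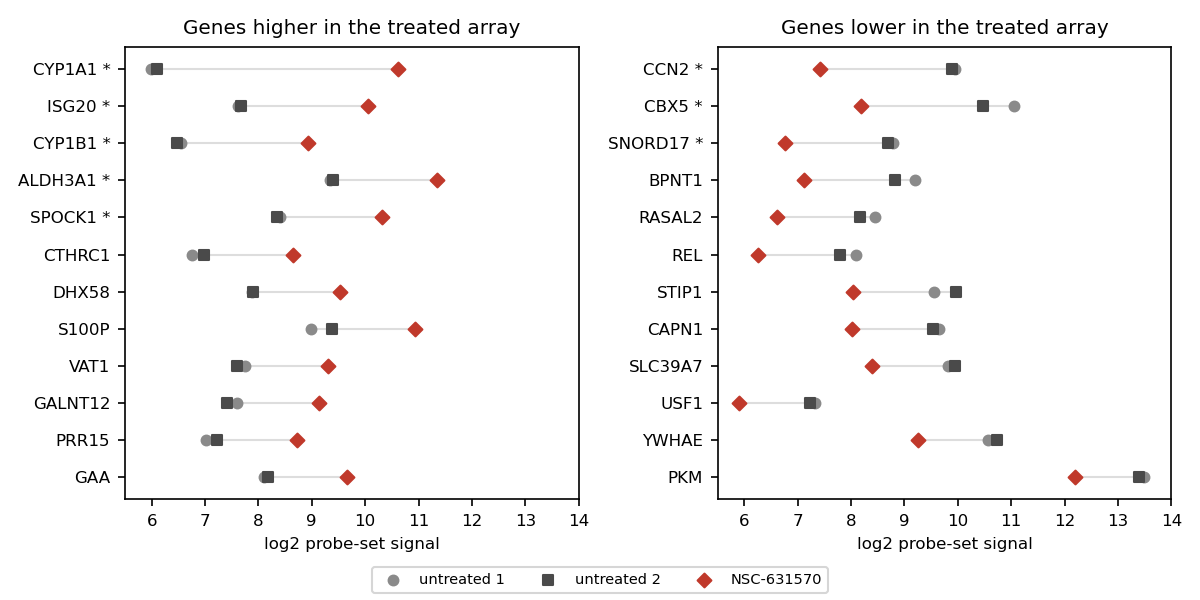
Signal of the 12 genes highest above and the 12 genes lowest below both untreated arrays, in log2 probe-set signal per array (circles and squares, the 2 untreated arrays; diamonds, the treated array); an asterisk marks the 8 genes with a limma adjusted p under 0.05. CYP1A1 lay at 5.99 and 6.10 in the untreated arrays and at 10.62 in the treated array, and CCN2 at 9.95, 9.90 and 7.41.

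Within the list of AhR and xenobiotic metabolism genes, the change was carried by few members. Of 12 tested, CYP1A1, CYP1B1 and ALDH3A1 rose and 9 did not pass the test over all genes. Adjusted over the list alone, 4 rose, with AHRR, the repressor of the receptor and itself a target, 1.88-fold higher (log2 difference 0.91), although its other probe set differed by 0.02. On their brightest probe sets, the receptor gene AHR (−0.07) and its partner ARNT (0.00057) differed from the untreated mean by less than the untreated arrays differed from each other (0.75 and 0.02). Both were named after their values were seen. The 2 other probe sets of AHR stood at a median of −0.57, and the 4 others of ARNT at −0.02. The list was higher by camera, a test of a gene list against all other tested genes (adjusted p = 0.00533, or 0.986 with an estimated correlation between genes, 10 of 12 members higher). With the filter at the 60th percentile camera gave 0.11. Its median of 0.21 lay within the range of random lists of the same size (percentile 79, adjusted p = 0.622), also without untreated replicate 1 (adjusted p = 0.81), but past the threshold without untreated replicate 2 (median 0.56, adjusted p = 0.015). The median was 0.02 with a common median over the tested genes and 0.06 with the mean of a gene's probe sets.

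Interferon-stimulated genes were higher as a group. Of 24 tested, 23 were higher than the untreated mean and 22 were above both untreated arrays. None passed the test over all genes and 16 rose adjusted over the list alone. The median log2 difference was 0.79, where random lists gave 0.11. IFI27 was 7.54-fold higher (2.92 ± 1.04), MX1, an antiviral GTPase, 4.20-fold (2.07 ± 0.55), IRF9, a subunit of the interferon-activated transcription factor, 3.09-fold (1.63 ± 0.42) and IFI44L 2.78-fold (1.48 ± 0.47). The list passed by camera (adjusted p = 6.95e-08, or 0.986 with an estimated correlation between genes). The smaller p-value takes the members as almost independent and measures no spread between arrays. The untreated arrays also differed in these genes: the median gap between them was 0.49, with untreated 1 the higher in 19 of 24, and the 2 values of IFI27 were 9.92-fold apart. The median distance of the treated array above the higher untreated array was 0.62. The list median was 1.07 without untreated replicate 1 and 0.66 without untreated replicate 2. With 1 array on each side, no spread between arrays could be measured there. From untreated 1 and untreated 2 singly the differences were 1.26 and 4.57 for IFI27, 1.05 and 2.21 for IRF9, and 0.80 and 2.16 for IFI44L, and the untreated values of MX1 were 1.66 apart.

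**Figure D2:**
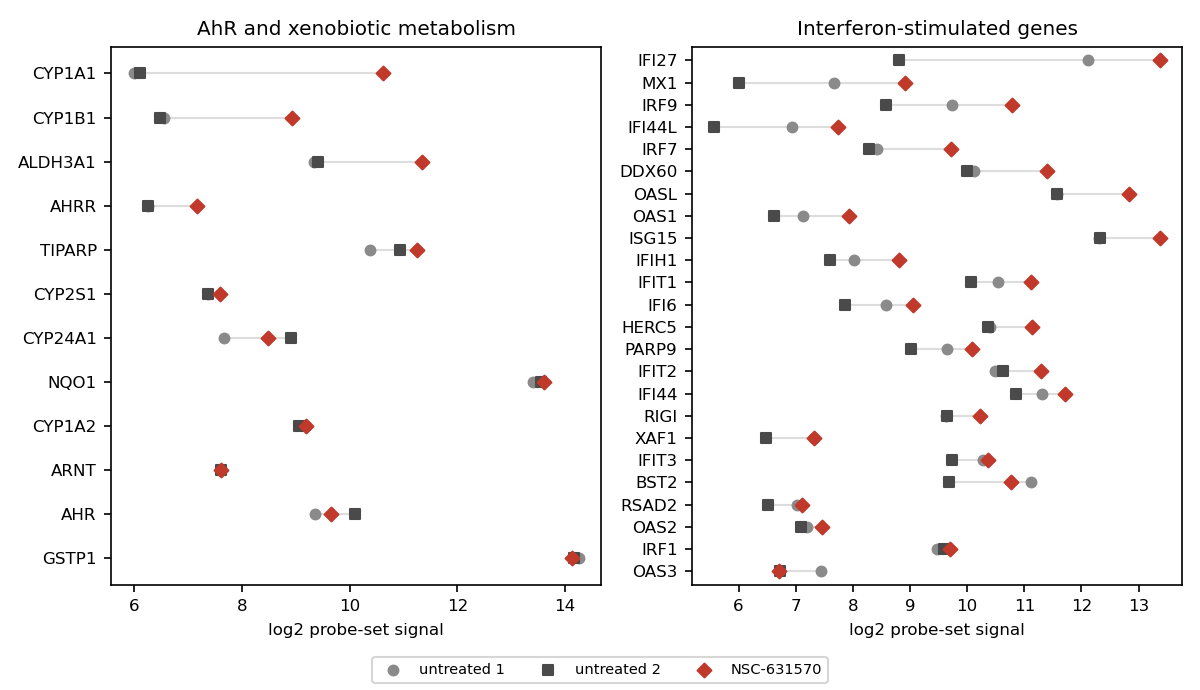
Members of the AhR and interferon lists, in log2 probe-set signal per array (circles and squares, the 2 untreated arrays; diamonds, the treated array), ordered by the difference of the treated array from the untreated mean. The AhR list differs in its first members, while 22 of 24 interferon-stimulated genes lie above both untreated arrays, several with a wide gap between the untreated arrays.

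Matrix proteases and their inhibitors were higher as a group, with 18 of 21 members above the untreated mean. None passed over all genes, and 3 rose adjusted over the list alone. These were the metalloproteinases MMP28 (log2 difference 1.46, 2.75-fold, its other probe set 0.17) and MMP1 (0.98, 1.97-fold) and the inhibitor TIMP1 (0.83, 1.78-fold). The lysosomal protease CTSL stood at 0.99. The list median was 0.45, and camera gave an adjusted p = 0.0118, or 0.986 with an estimated correlation and 0.143 with the filter at the 60th percentile. In other lists of the cell surface and matrix the direction was mixed. Among 21 genes for laminins, integrins and matrix adhesion CCN2 fell, and adjusted over the list alone 3 rose and 2 fell, with NID1 at 1.64 (its other probe set 0.53), the integrin genes ITGA2 at 1.32 and ITGB5 at 1.06 among those that rose. The median of that list was 0.32, past the threshold against random lists (adjusted p = 0.0472) but not by camera (adjusted p = 0.96). Among 15 YAP/TEAD targets, the genes read by the Hippo pathway, CCN2 fell and the related CCN1 was lower (−1.05), while NT5E (1.48) and ASAP1 (0.78, 3 other probe sets at a median of −0.05) were higher. Adjusted over the list alone, 2 rose and 2 fell in that list (camera adjusted p = 0.0552, random lists 0.0439). Among 14 TGF-beta targets, 2 rose adjusted over the list alone (LTBP2, 0.98, and SMAD3, 0.80, with 4 other probe sets at a median of −0.05) and CCN2 fell (camera adjusted p = 0.96). The difference from untreated 1 was 2.13 for NT5E and 1.41 for CTSL, and from untreated 2 it was 0.83 and 0.57.

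The next lists were measured in an array whose 5′ control probe set for ACTB was 2.59-fold lower and its 3′ one within 0.20 of the untreated mean. Of 20 NF-kB target and cytokine genes, 13 were below the untreated mean and none passed over all genes. Adjusted over the list alone 3 chemokine genes fell: CCL20 (−1.48, 2.79-fold lower), CXCL8 (−1.01) and CXCL1 (−0.93). CXCL2 stood at −1.18, while the cytokine genes IL24 (1.41) and IL36G (1.40) were higher. CXCL8 and CXCL1 are outside the fixed rule for naming genes and are named because the count is small. The list was lower by camera (median −0.29, adjusted p = 0.00203, or 0.986 with an estimated correlation between genes). Untreated 2 lay above untreated 1 by a median of 0.67 in this list, with IL36G, CXCL1 and TNF the other way. Without untreated replicate 2 the list median was 0.0045. Of 19 targets and feedback genes of ERK signalling, 4 fell and 2 rose adjusted over the list alone. The immediate early genes EGR1 (−1.38) and FOS (−1.27) were among those that fell, and the transcription factor genes ETV5 (1.21) and ETV4 (1.12) were those that rose. That list did not shift as a whole (median 0.09, camera adjusted p = 0.425). Differences from untreated 1 and untreated 2 singly were 2.38 and 0.44 for IL24, 0.68 and 2.12 for IL36G, −0.93 and −2.03 for CCL20, −0.61 and −1.75 for CXCL2, −0.82 and −1.72 for FOS, and 1.73 and 0.69 for ETV5.

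Of 25 genes of the unfolded protein and integrated stress response, 14 were below the untreated mean, and CALR, a chaperone of the endoplasmic reticulum, fell adjusted over the list alone (−1.28, 2.43-fold lower, its other probe set −0.37). ATF3 stood at −1.21, DDIT4 at −0.92 and CHAC1 at −0.79. The list was lower by camera (median −0.11, adjusted p = 0.025, or 0.986 with an estimated correlation between genes, 0.0813 without a filter and 0.0683 with a common median over the tested genes). Without untreated replicate 2 the median turned to 0.21 (adjusted p = 0.298 against random lists), since DDIT4 and most other members lay higher in that array, by a median of 0.70. Of 16 cholesterol synthesis genes 12 were lower, led by IDI1 (−0.44) and ACAT2 (−0.31), while INSIG1 was higher (0.32, other probe sets 0.08), and none passed adjusted over the list alone. This list also was lower by camera (median −0.13, adjusted p = 0.0229, or 0.986 with an estimated correlation between genes). Without untreated replicate 2 it missed the threshold against random lists (median −0.10, adjusted p = 0.0607). Taken from untreated 1 and untreated 2 singly, ATF3 differed by −0.77 and −1.65, DDIT4 by 0.03 and −1.87, CHAC1 by −0.20 and −1.38, and INSIG1 by 0.15 and 0.49.

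The lists for ribosome biogenesis, mitosis and DNA repair were also measured beside the 2.59-fold lower 5′ control signal of ACTB. Camera set these and the other lists against tested genes with a median of 0.12, so medians near 0 count as low. Of 20 ribosome biogenesis and MYC target genes 14 were lower, led by MRTO4 (−0.82), NOP58 (−0.64) and PES1 (−0.61), while MYC itself differed by −0.03 (named after its value was seen). Camera called the list lower (median −0.15, adjusted p = 0.00208, or 0.986 with an estimated correlation between genes). Of 27 genes of mitosis and G2/M 19 were lower, among them MKI67 (−0.46), DLGAP5 (−0.32) and PLK1 (−0.30), and the list was lower by camera (median −0.07, adjusted p = 0.0118, or 0.986 with an estimated correlation between genes). DNA repair genes were lower by camera as well (11 of 17 members, median −0.03, adjusted p = 0.0385), led by the histone variant gene H2AX (−0.61) and the checkpoint kinase gene CHEK1 (−0.39). With an estimated correlation the adjusted p = 0.986, and their median was 0.02 with arrays brought to a common median over all probe sets. Without a filter camera gave DNA repair an adjusted p = 0.068. Against random lists it did not pass (adjusted p = 0.164), nor without untreated replicate 2 (0.0813), but it did without untreated replicate 1 (0.0434). No member of these 3 lists passed, even adjusted over the list alone. From untreated 1 and untreated 2 in turn, PES1 differed by −0.36 and −0.87, MKI67 by −0.65 and −0.26, and MYC by 0.25 and −0.32.

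Of 15 replication-dependent histone genes, 9 were lower and 2 fell adjusted over the list alone, H4C8 (−1.11, 2.16-fold lower) and H2BC5 (−0.93), the second with 2 other probe sets at a median of 0.03. H2AC6 stood at −0.66 and H1-3 at −0.57. The histone list was lower by camera (median −0.11, adjusted p = 0.00309, or 0.986 with an estimated correlation between genes). Without untreated replicate 2 its median was 0.01 (adjusted p = 0.525 against random lists). The 27 genes of DNA replication and S phase did not pass by camera (median −0.02, adjusted p = 0.0829), with CCNE1 (1.18) and CCNE2 (0.85, its other probe set 0.11) higher and MCM5 (−0.89) and ORC1 (−0.70) lower. H2AC6 differed by −0.13 from untreated 1 and −1.18 from untreated 2, and CCNE2 by 0.46 and 1.23.

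Among 12 keratin and squamous lineage genes, KRT18 fell (−0.99, 1.99-fold lower) and KRT14, a keratin of basal cells, rose (0.95, 1.93-fold higher) adjusted over the list alone. KRT8, the partner of KRT18, stood at −0.60. KRT5, the partner of KRT14, was lower (−0.39, its other probe set −2.30), as were KRT15 (−0.27) and KRT19 (−0.23), all 3 named after their values were seen. The list was lower by camera (9 of 12 members, median −0.25, adjusted p = 0.0057, or 0.986 with an estimated correlation between genes and 0.102 with the mean of a gene's probe sets). Of 14 keratinocyte differentiation genes 11 were higher, with RHCG (1.18) past the threshold adjusted over the list alone and S100A9 at 1.28. That list did not pass by camera (adjusted p = 0.331) but did against random lists (median 0.38, adjusted p = 0.0392), and its members differed by a median of 0.45 between the untreated arrays. S100A9 differed by 0.16 from untreated 1 and 2.40 from untreated 2.

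The other lists did not pass by camera or against random lists. Drug efflux transporters had 7 of 10 members higher, near the share of all tested genes (7875 of 11933). ABCA1 (1.44), ABCC3 (1.35) and ABCC2 (0.78) rose adjusted over the list alone (camera adjusted p = 0.204). The other probe set of ABCC3 differed by −0.15, and the untreated values of ABCA1 were 1.28 apart. ANGPTL4 (1.34) rose among 16 genes of lipid metabolism, MT1F (1.04, its other probe set 0.34) among 10 of the metal response and NDRG1 (1.44, 5 other probe sets at a median of −0.16) among 24 of hypoxia and glycolysis, where PKM (−1.25) fell, each adjusted over the list alone. STIP1 fell in the same sense among 17 heat shock genes, while HSP90AA1 stood at −0.42 and DNAJB1 at 0.36 (other probe sets −0.15). No member passed, even adjusted over the list alone, among 21 p53 targets (CDKN1A 0.80, GADD45A −1.05), 21 apoptosis regulators (CASP8 −0.62, TNFSF10 0.50), 18 tubulin genes (TUBA1A 0.60), 20 NRF2 targets (AKR1C3 1.23, AKR1C1 0.85), 22 of autophagy and lysosome (WIPI1 0.90), 22 of oxidative phosphorylation (CYC1 0.45), 18 ribosomal proteins (RPL11 −0.38), 15 Wnt and Notch targets (HES1 0.76, 4 other probe sets at a median of −0.18), 11 of the EGFR family (ERRFI1 −1.13), 23 of epithelial junctions (PKP1 0.94) and 16 mesenchymal genes (ITGA5 1.05, CDH2 −0.87). Among markers of cells that the culture should not hold, 1 of 6 leukocyte genes rose adjusted over the list alone (CD68, a lysosomal protein, 1.46), none of 5 endothelial genes did, and 3 fibroblast markers had signal, at 0.66 (FBLN1, with 5 other probe sets at a median of −0.04), 0.06 (COL1A1) and 0.05 (PDGFRB). CD14 stood at 0.82 among the leukocyte genes, with untreated values 0.86 apart, and ENG at 0.56 among the endothelial genes. Members that differed by over 1.5 times more or less from a single untreated array, with the values from untreated 1 and untreated 2, were ABCA1 (0.81, 2.08), AKR1C3 (0.65, 1.80), AKR1C1 (0.46, 1.23), CDH2 (−0.24, −1.50), ITGA5 (1.41, 0.68), ERRFI1 (−0.68, −1.58), GADD45A (−0.63, −1.48), PKP1 (0.50, 1.39), TNFSF10 (−0.14, 1.15), TUBA1A (0.89, 0.30), CD14 (0.38, 1.25) and PDGFRB (−0.006, 0.10).

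In all, 11 of 35 tested lists passed by camera, 3 higher and 8 lower, none with an estimated correlation, and 12 passed against random lists. The estimated correlation rests on 1 residual degree of freedom, so that version could hardly call any list. Camera with the preset correlation takes members as almost independent, and random lists draw genes, not arrays. Passing either measures no spread between arrays. Because the median of all tested genes was shifted upward, lists near 0 count as low in both tests. A common median over the tested genes moved the medians of the 11 lists by −0.20 each, and one over all probe sets by 0.04. With the mean of a gene's probe sets the medians were −0.38 for the unfolded protein and integrated stress response, −0.32 for histones, −0.21 for cholesterol synthesis, −0.17 for DNA repair and −0.13 for mitosis. Without untreated replicate 1 they were −0.51 for NF-kB, −0.49 for the stress response, −0.31 for histones and −0.10 for DNA repair. Histones stood at −0.28 with the filter at the 60th percentile and DNA repair at −0.06 after quantile normalisation. Median, mean and camera differed in sign in 13 lists, all of them among the 24 that did not pass.

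**Figure D3:**
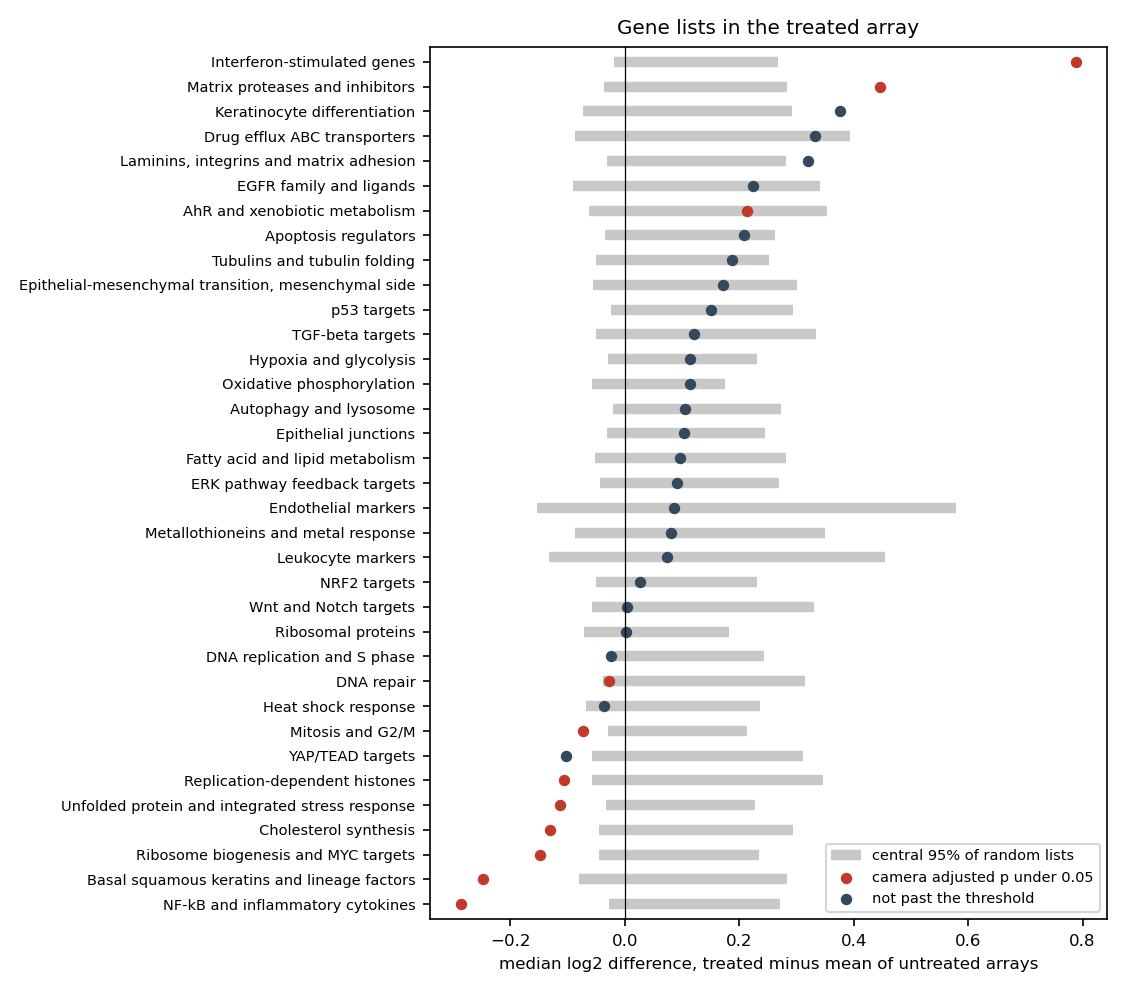
Median log2 difference between the treated array and the mean of the untreated arrays for the 35 gene lists tested (points; red, camera adjusted p under 0.05 with the preset correlation) and the central 95% of the medians of 10000 random lists of the same size matched on mean expression (grey bars). Interferon-stimulated genes lie highest at 0.79 and NF-kB and inflammatory cytokine genes lowest at −0.29.

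By size alone, 133 genes were at least 2-fold outside both untreated arrays, 105 higher and 28 lower. The same count with untreated 1 in place of the treated array gave 6 higher and 33 lower, and with untreated 2 it gave 31 higher and 29 lower. In each of these the treated array is 1 of the other 2, so they are no measure of what untreated arrays alone would give. An exact permutation of 3 arrays cannot give a p below 0.333. With a common median over the tested genes the split was 44 higher and 59 lower. With a single untreated array as the reference the count was 382 without untreated replicate 1 and 385 without untreated replicate 2. Many of these differences were not shared by the other probe sets of the same gene: of 57 higher genes with another probe set above the filter, 22 had a median of the others at least 1.5-fold higher, and of 20 lower genes 13 had a median at least 1.5-fold lower.

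The untreated arrays were closer to each other than to the treated one. Across genes, which are not independent replicates, the Pearson correlation was 0.985 for the untreated pair and 0.977 and 0.978 for the treated array against untreated 1 and untreated 2. The SD of the log2 differences was 0.33 in the untreated pair and 0.40 in both other pairs.

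Control probe sets along abundant transcripts gave lower signal toward the 5′ end of mRNA in the treated array, the array in which all higher and lower genes and lists above were measured. For the beta-actin gene ACTB the 3′ probe set differed by 0.20 from the untreated mean and the middle one by −0.09, while the 5′ one was 2.59-fold lower (−1.37). Its untreated values lay within 0.0027 of each other. For GAPDH the 3′ probe set differed by −0.01 and the 5′ one by −0.48. The 3 probe sets for 18S ribosomal RNA differed by −1.41 at the 3′ part, −1.18 in the middle and −1.63 at the 5′ part. Among the 4 spike-in transcripts, which are added before labelling, the difference between the 3′ and 5′ probe sets changed by 0.14 (Dap), 0.0068 (Lys), −0.28 (Phe) and 1.31 (Thr). Tested one by one, 29576 probe sets held 191 at least 2-fold higher and 764 at least 2-fold lower than in both untreated arrays, the reverse of the balance for genes taken by their brightest probe set.

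**Figure D4:**
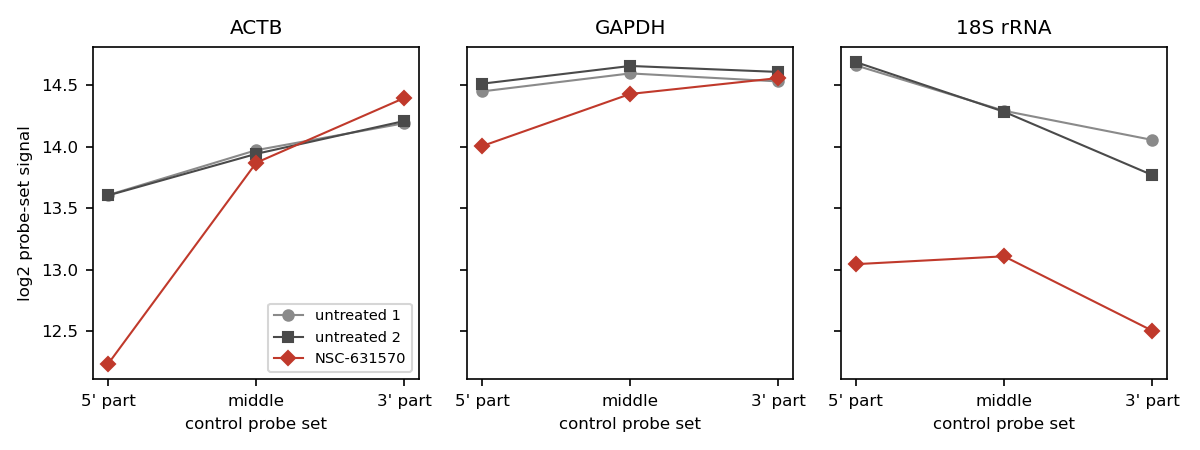
Log2 signal of the control probe sets at the 5′ part, middle and 3′ part of the ACTB, GAPDH and 18S ribosomal RNA transcripts in each array (circles and squares, untreated; diamonds, treated). The treated array differs from the untreated mean by −1.37 at the 5′ part of ACTB and by 0.20 at its 3′ part, and all 3 probe sets for 18S ribosomal RNA are lower.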

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

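The tests on interferon-stimulated genes, on S phase genes and on the brightest probe sets of genes were chosen after the results were seen.

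The array's own control probe sets stood out in the treated array, at least 2-fold outside both untreated arrays: the 5′ probe set of ACTB differed by −1.37 from the untreated mean, and the 18S ribosomal RNA probe sets by −1.41 at the 3′ part, −1.18 in the middle and −1.63 at the 5′ part. For mRNA such as ACTB, a candidate explanation is that shorter RNA or shorter labelled product lost signal away from the 3′ end. The 18S probe sets lack that pattern: their 3′ part was lower too, and their 3′ to 5′ difference changed by 0.22. Of 15323 probe sets other than the brightest of their gene, 673 in 498 genes were at least 2-fold lower. But the median difference of the brightest probe set of those genes was −0.0061 (95% bootstrap interval −0.03 to 0.02). In the same count 9.81% of the lower probe sets had a brightest probe set at least 1.5-fold lower. With untreated 1 set apart in place of the treated array this share was 90% of 40 lower probe sets. With untreated 2 it was 55.2% of 29. There the treated array is among those compared against, so probe sets that lost signal in it could hardly be counted. The brightest probe set was chosen by a mean that includes the treated array, which disfavours a probe set that dropped there. The contrast of 9.81% with these shares, and the median of −0.0061, are therefore partly built in. How large that part is was not tested. But the brightest probe set only stands in for the 3′ end, since probe set positions were not used here, so a change of isoforms stays open too. For the 20 genes that were 2-fold lower on their brightest probe set, the others kept a median share of 0.713 of the difference (0.389 to 0.983), and for 57 higher genes 0.384 (0.265 to 0.523), which leaves open how many single calls are of this kind. The spike-in transcripts were split, with Thr changed by 1.31 between its 3′ and 5′ probe sets and Lys by 0.0068, and because 1 array carries both the treatment and the RNA, an effect of the extract on RNA integrity and a difference in preparation cannot be told apart for the share kept by these genes.

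Interferon-stimulated genes were higher in the treated array by a median of 0.79. The upward shift of all tested genes is excluded as the source, since the list median lay above all 10000 random lists (percentile 100). Whether untreated cells vary in interferon signalling by as much is open: over the members, the distance above the higher untreated array minus the gap between the untreated arrays had a median of −0.0341 (95% bootstrap interval −0.43 to 0.37). This interval is over the 24 members, so it cannot show how far further untreated cultures would vary. For the 9 members with an untreated gap under 0.25 the median distance was 0.74. A response to the extract remains open and untested, since there is 1 treated array.

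Replication-dependent histone genes were lower by a median of −0.11. One candidate explanation is a lower yield of RNA without a poly(A) tail, as the lower 18S signal could suggest, but 20 small nucleolar and Cajal body RNAs lay at percentile 8.76 of random lists, with 6 below and 7 above both untreated arrays, so it stays open. Fewer cells in S phase is another, and the median of the S phase list lay at percentile 2.03, but its members went both ways around −0.02, so this does not decide it either. Without untreated replicate 2 the histone median was 0.01.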

How the results depend on the processing

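The centring over the tested genes, the count of agreeing probe sets and the alternatives for control probe sets and array similarity were chosen after seeing the data. CYP1A1, ISG20 and CCN2 passed in all 10 tested alternatives (highest adjusted p 0.0121, 0.0447 and 0.0447), CYP1B1 in 8 of 9, and ALDH3A1, SPOCK1, SNORD17 and CBX5 in 6 of 10 each. The log2 differences of ISG20, ALDH3A1, SPOCK1 and SNORD17 stayed the same with the mean of a gene's probe sets. For these genes the alternatives on probe sets could not show a disagreement between probe sets. The limma count of 8 genes became 4 with quantile normalisation, with no filter and with a bound of 0.5, 3 with the mean of a gene's probe sets, 21 with the filter at the 60th percentile, 31 with a trend in the prior variance, 50 and 136 with the common medians over tested genes and over all probe sets, and 970 (189 higher, 781 lower) over probe sets one by one; it was 8 with a robust prior. The number of genes 2-fold outside both untreated arrays, 133, was 87 with the filter at the 60th percentile, where fewer genes are tested, 955 over probe sets one by one, 844 at 1.5-fold, 35 where other probe sets had to differ too, and 382 to 385 with a single untreated array. With the mean of a gene's probe sets it was 108, with 47 higher and 61 lower. The 11 lists past camera became 0 with an estimated correlation, which rests on 1 residual degree of freedom and could hardly call any list. They lay between 9 and 13 under the other alternatives that used camera. The random-list test passed 12 lists, and 15 and 11 without untreated replicate 1 and 2. In that test 1 list turned direction, the unfolded protein and integrated stress response (median −0.11), at −0.49 without untreated replicate 1 and 0.21 without untreated replicate 2. The medians of 3 other lists changed sign: NF-kB (0.0045) and histones (0.01) without untreated replicate 2, and DNA repair (0.02) with a common median over all probe sets. Over the named genes 146 tested values stayed on their side of the threshold, 75 moved past it and 17 lost it, and 48 values against a single untreated array, without a test, kept their direction. Over the lists called by camera, 60 values stayed past camera and 17 lost it, and 25 stayed past the random-list test, 7 did not pass it and 1 turned. The 3′ to 5′ difference of ACTB changed by 1.57, and by 1.54 after quantile normalisation. Apart from the filter at the 60th percentile, the cause of these changes was not tested. Without an untreated array limma has no residual degrees of freedom, so its count has no value there. No paired analysis was possible because the treated group has 1 array. Background estimates were not used here, so how far signal over background limits genes near the filter of 5.85 was not tested.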

Other observations

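The comparison of probe sets was chosen after the results were seen. At least 2-fold differences between the untreated arrays were found for 158 tested genes, of which the 20 with the largest gaps, genes with only cross-hybridising probe sets left out, are named here after their values were seen. Untreated 1 was higher in IFI27 (9.92-fold), in the secreted protease MMP7 (5.16-fold), in the elastase inhibitor PI3 (5.14-fold), in S100A9 (4.75-fold), in the transcription factor gene EGR3 (3.83-fold), in the antiprotease SLPI (3.80-fold), in lipocalin LCN2 (3.44-fold) and in KRT4 (3.34-fold). Untreated 2 was higher in THBD (4.16-fold), SPX (4.15-fold), the cytokine IL24 (3.84-fold), the phosphatase DUSP1 (3.83-fold), the stress genes DDIT4 (3.72-fold) and DDIT3 (3.63-fold), INHBE (3.62-fold), TSC22D3 (3.61-fold), the thioredoxin inhibitor TXNIP (3.58-fold), the cytokine LIF (3.52-fold), PHLDA1 (3.49-fold) and GDA (3.41-fold). The treated array lay nearer to untreated 1 in 13 of the 20 and nearer to untreated 2 in 7. It lay near untreated 1 for DDIT4 (12.20 against 12.18 and 14.08), DDIT3 (7.71 against 7.51 and 9.37) and DUSP1 (9.69 against 9.76 and 11.70), and above both for SLPI (11.08 against 10.55 and 8.63).

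Some genes had at least 1 probe set far lower in the treated array while their brightest probe set was not. In ZNF664 the 2 lowest differed from the nearer untreated array by −4.08 and −4.01 on the log2 scale, and the brightest differed from the untreated mean by −0.0021. The same held for DDB1 (−3.41 and −0.07), DYNLL2 (−2.92 and −0.12) and EIF4H (−2.87 and 0.02). In CCN2 both differed alike (−2.54 and −2.51).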
